A study of Mus musculus with 2 samples.

How the data were processed

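The series holds 2 sequencing libraries of RNA recovered by immunoprecipitation from RAW 264.7 cells, a mouse macrophage cell line. Per the labels' protocols, the cells were depleted of mRrp6, the nuclear exosome ribonuclease encoded by Exosc10, and were stimulated with LPS at 80 ng/ml for 12 h. Nuclei were isolated in a hypotonic buffer, nuclear extracts were incubated with antibody and protein G beads, and the eluted RNA was treated with DNase, converted to double-stranded cDNA and sonicated. One library came from rabbit IgG (the control) and the other from an antibody against nucleolin. The library titled as nucleoplasmic RNA was taken as the nucleolin library, because the design text of the series describes nucleoplasmic RNA recovered with that antibody and the matching column carries the nucleolin symbol NCL.

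The deposited table gives FPKM, that is fragments scaled by transcript length and by the mapped fragments of the library, for 33529 transcript rows, with 1 column per library, per the file headers. Per the submitters' processing notes, FastQC 0.10.0, Trimmomatic 0.32 and the mm10 genome build were used. The aligner, the quantification tool, the treatment of reads with several alignments and the use of strand are not given in the sources used here. The rows carry RefSeq transcript accessions, gene identifiers and symbols. A gene symbol was missing in 56 rows, which held 0.0364% of the summed FPKM of the IgG library and 0.0794% of that of the nucleolin library, and these rows were left out of all gene comparisons. The remaining rows were summed to 23924 gene symbols, of which 5166 had more than 1 row. For repeated loci the table lists the same transcript several times (371 rows are marked as copies), so the sum for such a gene counts each listed copy. Gene identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 stands for, and 99.7% of them were found. Gene positions and types come from that table. Genes with near-identical copies, such as histone and ribosomal protein genes and their pseudogenes, and overlapping genes on opposite strands are uncertain, since the assignment of shared reads is not known.

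Values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. A gene was compared if it reached 1 FPKM in at least 1 library. The difference was log2((nucleolin FPKM + 1) / (IgG FPKM + 1)), that is with a pseudocount of 1, which understates the change of low genes. Differences of 2-fold or more on this scale were counted. With 1 library per group nothing measures the spread between replicates, so no test between groups was made and no p-value is given. A gene below 0.1 FPKM in a library is described as at or near 0 there, and no fold is given against such a value. Each gene list, fixed before the data were examined, was summarised by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins. These percentiles describe the 2 libraries and are not tests of the conditions.

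The depth of each library was not stated, and it was examined through the low values. Among genes with 1 transcript row and values in both libraries, the ratio of the FPKM values is a ratio of whole reads multiplied by a constant, the worth of 1 read in one library over the other. That constant was taken from the most frequent ratio, and each ratio was matched to the smallest pair of whole reads (at most 8 in all) within 0.05 on the log2 scale. Genes below 60 FPKM in the IgG library and 30 FPKM in the nucleolin library were used, limits set after seeing the data. Where a pair was found, an exact (Clopper-Pearson) 95% interval of the FPKM ratio was computed from it. These intervals are the widest possible, since the true read numbers may be a multiple of the pair, and they cover counting error only. Total read numbers were not recovered, because the table gives no transcript lengths. The steps were run on simulated data built to meet their assumptions. In deep simulated libraries with little noise, all (100%) of the 4-fold changes were recovered among 572 genes. In shallow ones without noise, 100% of 1476 read pairs were recovered in lowest terms. These runs check the computation only, not whether the real libraries meet the assumptions.

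Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 15 largest and 10 smallest log2 ratios among genes 2-fold or more apart with a mean level above the median of compared genes, the 5 highest genes of each library, Exosc10 and Ncl. It also takes, from each list with at least 3 measured members, the 2 members with the largest and the 2 with the smallest ratio above that same level. A gene that the rule takes is not reported here. Other genes named are members of lists fixed beforehand, or are said to be chosen after their values were seen. The naming of such list members, for example Krt8 and Rpph1, was not fixed beforehand. Alternatives set at the start were the filter on low values, the pseudocount, 3 other scalings between the libraries, the highest row per gene in place of the sum, other fold thresholds, random lists without matching, and shares without the highest genes. Further alternatives were added after the data were seen. They were genes measured in both libraries only, summed FPKM per list, and a scaling that sets 1 read equal in both libraries. Another kept only genes that, in at least 1 library, were above the highest FPKM at which any gene was at the ratio of equal reads. No transcript encoded by the mitochondrial genome was listed, so leaving them out of the shares changes nothing. The table holds no comparison or region list by the authors, so none was described.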

Results

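RNA associated with nucleolin, an abundant nucleolar RNA-binding protein, was sequenced after immunoprecipitation from nuclear extracts of LPS-stimulated, mRrp6-depleted RAW 264.7 macrophages. The study asked which transcripts nucleolin targets, and an IgG immunoprecipitation of the same cells gave the background. There was 1 nucleolin library and 1 IgG library, so no difference below has a replicate check. The table listed 2009 genes at 0.1 FPKM or more in the IgG library and 1729 in the nucleolin library, of which 538 were in both. Depth was very low. Of 246 low genes with 1 transcript row and a value in both libraries, 157 (63.8%) had the same nucleolin-to-IgG ratio of 0.393 within the tolerance, the ratio that equal read numbers give, most simply 1 read in each library. Another 31 lay at the ratio of 1 IgG read to 2 nucleolin reads and 17 at 2 to 1. In all, 98.8% lay at a ratio of small whole numbers, while the tolerance windows covered 36.0% of the range of ratios. At 1 read in each, a gene had a median of 17.2 FPKM in the IgG library and 6.76 FPKM in the nucleolin library, so 1 read was worth 2.54 times more FPKM in the shallower IgG library. A gene with equal reads in both therefore appeared lower in the nucleolin library, with a median log2 ratio of -1.23 on the scale used here.

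**Figure D1:**
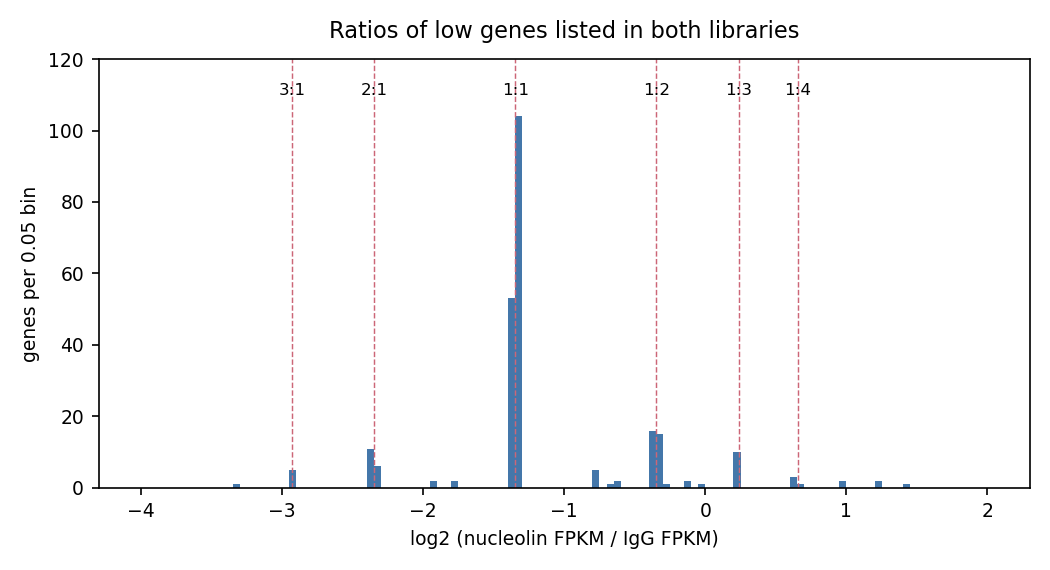
Number of genes (vertical axis, per 0.05-wide bin) by the log2 ratio of nucleolin FPKM to IgG FPKM (horizontal axis), for low genes with 1 transcript row that were listed in both libraries; dashed lines mark whole-read ratios, IgG reads first. Most genes (157 of 246) sit in the peak at 1:1, and further peaks sit at 1:2 and 2:1.

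The target of the depletion, Exosc10, was at 0 FPKM in the IgG library and 6.42 FPKM in the nucleolin library, near the worth of 1 read. Both libraries came from depleted cells, so these values do not check the depletion. Of 21 genes for exosome subunits and cofactors, 6 were measured, 4 of them higher and 2 lower in the nucleolin library; Exosc5 was at 20.6 FPKM there and 0 in the IgG library. The list's median log2 ratio of 2.34 lay at the 79th percentile of random lists. Ncl, which encodes nucleolin, was at 5.25 FPKM in the IgG and 6.14 FPKM in the nucleolin library, at the ratio of 1 to 3 reads, with a 95% interval of the FPKM ratio from 0.0948 to 62.0.

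The nucleolin library contained macrophage and LPS-response transcripts that were at or near 0 in the IgG library. They included Lyz2 (lysozyme of myeloid cells, 199.6 FPKM), Isg15 (an interferon-induced ubiquitin-like protein, 126 FPKM), Mif (a macrophage cytokine, 103 FPKM), Tnf (81.0 FPKM) and Ifitm3 (an interferon-induced antiviral membrane protein, 79.4 FPKM). The IgG library contained transcripts of digestive and gastric secretory proteins that were listed at 0 in the nucleolin library. These were Pgc (pepsinogen C, 5078 FPKM), Clps (colipase, 4349 FPKM), Pla2g1b (a secreted phospholipase, 3265 FPKM), Tff1 (a gastric trefoil peptide, 2915 FPKM), Gkn2 and Gkn1 (gastrokines, 1545 and 1163 FPKM) and Chia1 (acidic chitinase, 1503 FPKM). Of 3194 genes compared, 1206 were at least 2-fold higher and 1812 at least 2-fold lower in the nucleolin library. Of the higher genes 1186 were at or near 0 in the IgG library, and of the lower genes 1470 were at or near 0 in the nucleolin library. Counted over the 538 genes measured in both, the numbers were 20 higher and 342 lower. Of the latter, 154 were low genes with 1 transcript row at the ratio of equal reads. Genes with more rows or higher values were not examined for this count. The median log2 ratio of the 538 genes was -1.19, near that of equal reads (-1.23). Medians over list members in both libraries stand against that value, not against 0. The highest levels at which any gene was at the ratio of equal reads were 178 FPKM in the IgG and 70.3 FPKM in the nucleolin library. Among the 129 genes above this level in at least 1 library, 27 were higher and 61 lower. These include genes at or near 0 in the other library, such as Isg15 and Pgc.

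**Figure D2:**
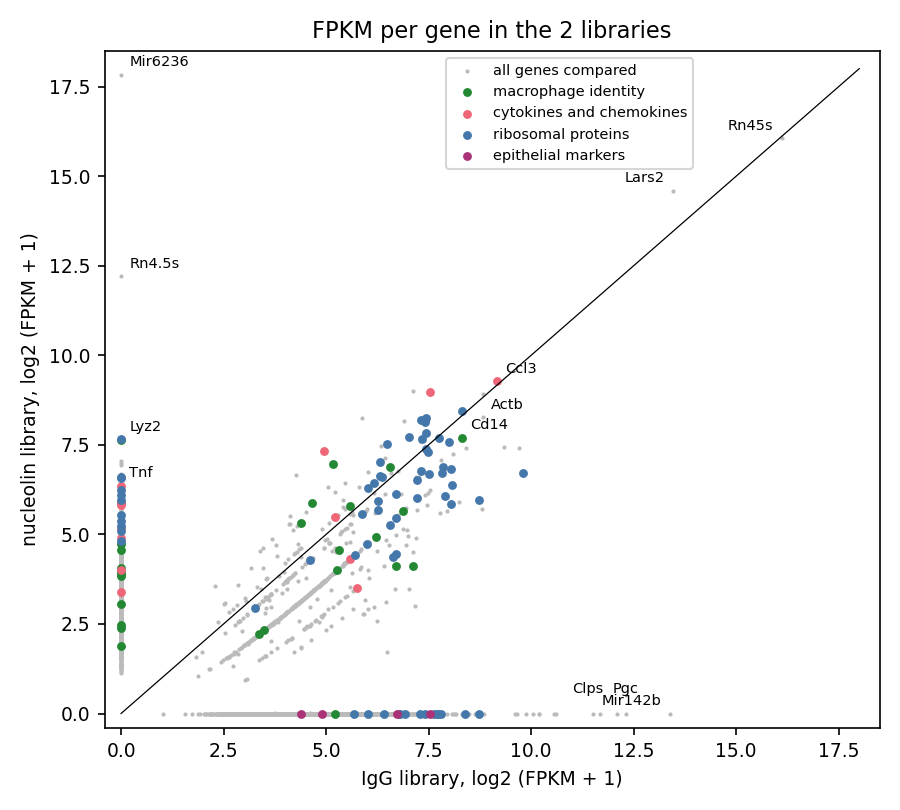
Each point is a gene, with log2(FPKM + 1) in the IgG library on the horizontal axis and in the nucleolin library on the vertical axis; the line marks equal values and colours mark 4 gene lists fixed beforehand. Most genes lie on an axis, at or near 0 in the other library, and the 4 listed epithelial markers lie on the IgG axis.

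The remaining genes with the largest ratios were ribosomal protein genes and genes of other functions. Rpl23a (202 FPKM), Rps10 (96.8 FPKM), Rps13 (94.4 FPKM) and Rpl24 (73.8 FPKM) were listed in the nucleolin library and at 0 in the IgG library. So were Sdf2l1 (an endoplasmic reticulum protein, 132 FPKM), S100a11 (a calcium-binding protein, 121 FPKM), Atox1 (a copper chaperone, 80.0 FPKM) and Prdx5 (a peroxiredoxin, 72.4 FPKM). Rmrp (the RNA of RNase MRP, 1061 FPKM) was listed only in the IgG library. On mm10, Lyz2 lies on chromosome 10 from 117277541 to 117282272, Isg15 on chromosome 4 from 156199424 to 156200818 and Tnf on chromosome 17 from 35199367 to 35202007. Pgc lies on chromosome 17 from 47726842 to 47734478, Clps on chromosome 17 from 28558210 to 28560766, Tff1 on chromosome 17 from 31161395 to 31165060 and Rmrp on chromosome 4 from 43492785 to 43493059.

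Ribosomal RNA took a large part of both libraries. Rn45s, the 45S ribosomal RNA precursor, was at 70761 FPKM in the IgG and 68377 FPKM in the nucleolin library, a log2 ratio of -0.05 as deposited that turned to 1.22 when centred on all genes and to 1.30 with 1 read set equal. Lars2, listed as mitochondrial leucyl-tRNA synthetase, was at 11227 and 24793 FPKM, 2.21 times higher in the nucleolin library. Mir6236, a microRNA gene on chromosome 9 from 110281287 to 110281409, was at 232751 FPKM in the nucleolin library and 0 in the IgG library, and took 64.3% of the nucleolin library's summed FPKM. Mir142b, on chromosome 11 from 87756841 to 87756955, showed the opposite, with 10684 FPKM in the IgG library and 0 in the nucleolin library. Rn4.5s, a 4.5S RNA listed in several copies, summed to 4741 FPKM in the nucleolin library and 0 in the IgG library. These 3 were the shortest of the compared genes with a known span, with spans of 123, 115 and 174 bases, and FPKM divides by length. The 10 highest genes held 59.1% of the summed FPKM of the IgG library and 92.1% of that of the nucleolin library. Without Rn45s, Lars2, Mir6236 and Mir142b, the sum over all other genes was 97649 FPKM in the IgG and 35976 FPKM in the nucleolin library, 2.71 times higher in the IgG library.

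Inflammatory cytokine and chemokine genes stood toward the nucleolin library. Of 26 listed genes induced through NF-kappa B, 13 were measured, 9 of them at least 2-fold higher in the nucleolin library and 2 lower. Cxcl2, a neutrophil-attracting chemokine, was at 58.0 FPKM in the nucleolin library and 0 in the IgG library, as Tnf was at 81.0 and 0. Ccl22 was at 52.5 FPKM in the IgG and 10.4 FPKM in the nucleolin library, at the ratio of 2 to 1 reads with a 95% interval from 0.00333 to 3.78, and Cxcl10 was at 47.1 and 19.0 FPKM, the ratio of equal reads. All 4 measured epithelial markers (below 0.1 FPKM in the nucleolin library) were on the other side, with Krt8 at 185 FPKM in the IgG library. Ccl3, the highest messenger RNA of a cytokine in both libraries, was at 575 and 620.4 FPKM, a ratio of 1.08. Its log2 ratio of 0.11 as deposited moved to 1.38 when centred on all genes and to 1.45 with 1 read set equal. The list's median log2 ratio was 3.38, above all 10000 random lists (100th percentile), against a median of -1.27 over all genes compared. Over the 6 members measured in both it was 0.18, and the summed FPKM was 926 in the IgG and 1637 in the nucleolin library.

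Macrophage identity genes showed the same direction by their median, and it rested on genes not listed in the IgG library. Of 35 genes, 27 were measured, 14 at least 2-fold higher and 8 lower in the nucleolin library, and 12 were at or near 0 in the IgG library against 1 in the nucleolin library. Coro1a (a leukocyte actin regulator, 57.6 FPKM) and Lyz2 were listed at 0 in the IgG library. Cd68, a lysosomal glycoprotein of macrophages, was at 138 FPKM in the IgG and 16.2 FPKM in the nucleolin library, and Ms4a6d at 36.2 and 0. The median log2 ratio was 1.21 (100th percentile). It was -0.94 over the 14 members measured in both, against -1.19 over all genes in both. The summed FPKM was 1099 in the IgG and 1135 in the nucleolin library. The epithelial markers Krt8 and Krt18 were at 185 and 106 FPKM in the IgG library and 0 in the nucleolin library beside them.

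Other LPS-response genes were mixed. Of 41 interferon-stimulated genes 15 were measured, 9 higher and 5 lower in the nucleolin library. Their median of 2.17 (99.3rd percentile) was -1.21 over the 4 measured in both, near the -1.19 of all genes in both. At a minimum of 10 FPKM, 5 were higher and 5 lower (median 0.60), and after centring on all genes 10 were higher and 2 lower. The floor of 10 FPKM is not neutral. It tends to drop genes at 1 nucleolin read (median 6.76 FPKM) and to keep those at 1 IgG read (median 17.2 FPKM). Oasl1, an oligoadenylate synthetase-like protein, was at 17.4 FPKM in the nucleolin library and 0 in the IgG library, while Igtp, an interferon-induced GTPase, was at 23.2 FPKM in the IgG library and 0 in the nucleolin library, as was Xaf1 on a lower IgG value. Of 15 measured other LPS-induced genes 6 were higher and 6 lower, with a median of 0.21 (94.8th percentile) that was -0.02 over the 7 measured in both and -1.26 at a minimum of 10 FPKM, and their summed FPKM was lower in the nucleolin library (a log2 ratio of -0.56). Ptgs2, the inducible cyclooxygenase, was 2.48 times higher in the nucleolin library (32.1 against 79.8 FPKM), and Slc7a11, a cystine transporter, was at 4.68 and 7.30 FPKM, at the ratio of 1 to 4 reads with a 95% interval from 0.156 to 77.5. Lcn2 and Slpi, which are also epithelial secretory products, were at 65.0 and 62.7 FPKM in the IgG library and 0 in the nucleolin library. Of 13 measured immediate early genes 4 were higher and 7 lower. Their median of -1.26 turned to 0.01 when centred on all genes; Dusp5 was at 17.8 FPKM in the nucleolin library only, Ier3 at 47.6 and 38.4 FPKM (a log2 ratio of -0.30 that turned to 0.96 after centring), and Ier2 and Myc at 32.0 and 19.2 FPKM in the IgG library only. No member of the list of LPS-regulated long non-coding RNAs (7 in the table) was above 0.

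Beside these groups, markers of another cell type differed between the libraries. Of 6 epithelial markers 4 were listed in the IgG library and 0 in the nucleolin library: Krt8 (185 FPKM), Krt18 (106 FPKM), Krt14 (29.0 FPKM) and Cdh1 (20.1 FPKM). Their median log2 ratio of -5.82 lay at the 0.18th percentile of random lists. Apoa1 of the hepatocyte list (215 FPKM) and Col1a1 and Col3a1 of the fibroblast list (18.8 and 15.8 FPKM) were also listed in the IgG library only. In the T cell list only Lck was listed, at 8.92 FPKM in the nucleolin library. No marker of B cells, endothelial cells, erythroid cells, neurons, neutrophils or mast cells reached 1 FPKM in either library.

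Genes for nucleolar and ribosome biogenesis proteins were listed more often in the nucleolin library. Of 28 genes 14 were measured, 10 higher and 2 lower in the nucleolin library, and 10 of the 14 were at or near 0 in the IgG library. At a minimum of 10 FPKM, which tends to drop genes at 1 nucleolin read, 7 genes remained, 4 higher and 2 lower. Npm1 (nucleophosmin, 41.5 FPKM) and Nhp2 (an H/ACA ribonucleoprotein component, 21.3 FPKM) were listed in the nucleolin library only, and Nop10 (78.9 FPKM) in the IgG library only. Nolc1 was at 12.2 and 4.79 FPKM, the ratio of equal reads. The median was 2.82 (99.7th percentile). Over the 3 members measured in both it was -0.31, against -1.19 over all genes in both. Of 15 measured messenger RNAs on the list of reported nucleolin targets, 1 was higher and 11 lower in the nucleolin library, with a median of -2.20 (26.7th percentile). Centred on all genes, 3 were higher and 5 lower, with a median of -0.93. Hspa5, an endoplasmic reticulum chaperone, was at 54.4 and 78.5 FPKM, and Gpx4 and Sepp1, both selenoprotein genes, were listed in the IgG library only, at 62.5 and 23.3 FPKM.

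Ribosomal protein genes had the most measured members, 66 of 84, with 41 measured in both libraries. In the nucleolin library 12 were higher, 28 lower and 26 less than 2-fold apart. Their median of -0.57 (99.8th percentile) stood above that of all genes and turned to 0.69 when centred on it, with 27 higher and 16 lower. Rpl32 (421 FPKM) and Rps28 (335 FPKM) were listed in the IgG library only. Of 15 measured translation factor genes with 5' TOP motifs, 6 were higher and 6 lower, with a median of -0.31 (93.9th percentile) that turned to 0.96 after centring, with 7 higher and 2 lower. Pabpc1, the cytoplasmic poly(A)-binding protein, was 2.36 times higher in the nucleolin library (16.1 against 38.1 FPKM), Eef2 was at 146 and 28.6 FPKM, and Fau at 459 FPKM in the IgG library only. Of 25 measured housekeeping genes 4 were higher and 10 lower; their median of -0.68 (72.6th percentile) turned to 0.59 after centring, with 10 higher and 5 lower, and Gapdh was 2.40 times higher in the nucleolin library (118 against 284 FPKM). Hsp90aa1 was listed at 18.8 FPKM in the nucleolin library only, and Tbp and Ywhaz at 25.8 and 23.5 FPKM in the IgG library with values at or near 0 in the other. Of 22 measured endoplasmic reticulum genes 9 were higher and 3 lower, with a median of 0.38 (99.9th percentile, 85.4th without matching on level). It was -0.31 over the 13 measured in both, against -1.19 over all genes in both. Sec61b and Ssr4, of the protein translocation machinery, were at 51.6 and 36.3 FPKM in the nucleolin library only, Herpud1 at 76.0 FPKM in the IgG library only, and Ssr1 at 9.28 and 1.81 FPKM, the ratio of 2 to 1 reads.

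Among nuclear RNAs, Malat1 and Neat1, long non-coding RNAs of nuclear speckles and paraspeckles, differed in direction. Malat1 was at 18.7 FPKM in the IgG and 36.5 FPKM in the nucleolin library, and Neat1 at 28.4 and 5.58 FPKM, the latter at the ratio of 2 to 1 reads with a 95% interval from 0.00333 to 3.78. Of the 3 measured members of that list 2 were lower, Tug1 at 9.33 FPKM in the IgG library and 0 in the nucleolin library, and the median was -2.16 (36.0th percentile). Of 1074 microRNA genes only Mir6236 and Mir142b were measured. No box C/D snoRNA (70 in the table), box H/ACA snoRNA (34), small Cajal body RNA (9) or small nuclear RNA (5) was above 0 in either library. Of the other small non-coding RNAs, Rpph1, the RNase P RNA, was at 340.0 and 169.8 FPKM. Of the snoRNA host genes only Gas5 (17.97 and 7.08 FPKM, the ratio of equal reads) and Snhg12 (105 FPKM in the IgG library, 0 in the nucleolin library) were measured.

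As deposited, most measured histone and splicing factor genes were lower in the nucleolin library, as were most genes compared. After centring on the median of all genes (-1.27), 19 of 22 histone genes were 2-fold lower. So were 12 of 26 splicing factor genes and 1485 of 3194 genes compared. The 19 histone genes were at or near 0 in the nucleolin library, with log2 ratios of -3.09 or lower as deposited. Centring could therefore not bring them within 2-fold, and their unchanged number is no added evidence. Of 22 measured replication-dependent histone genes 19 were lower and 2 higher in the nucleolin library, with a median of -4.26 (11.8th percentile, random median -4.14, but 0.24th percentile without matching on level). Hist1h2be (136 FPKM) and Hist1h1d (73.7 FPKM) were listed in the IgG library only, and Hist1h3e (69.3 FPKM) and Hist2h3b (40.8 FPKM) in the nucleolin library only. Reads shared among histone copies make single members uncertain. Some copies had identical IgG values, so counts of histone genes need not be counts of independent genes. Of 26 measured splicing factor genes 19 were lower and 6 higher, with a median of -1.65 (51.4th percentile, random median -1.69, and 48.0th without matching). Rbm39 and Clk1 were at 53.2 and 51.9 FPKM in the IgG library only, Hnrnpa2b1 was 2.21 times higher in the nucleolin library (21.8 against 48.2 FPKM), and Ptbp1 was at 15.6 and 11.7 FPKM, a log2 ratio of -0.38 that turned to 0.89 when centred on all genes. Zinc finger genes (32 measured of 432, 14 higher and 18 lower) had a median of -1.90 (10.4th percentile). At a minimum of 10 FPKM, 1 was higher and 13 lower, with a median of -3.60. That floor tends to drop genes at 1 nucleolin read, and over all genes it left 448 higher and 1439 lower. Zfp771 was at 16.5 FPKM in the nucleolin library only, Zfp809 at 32.7 FPKM in the IgG library only, and Zfp384 (14.4 and 5.66 FPKM) and Zfp91Cntf (13.4 and 5.27 FPKM) were at the ratio of equal reads. Of 9 measured cell cycle genes 5 were higher and 4 lower, with a median of 1.42 (56.6th percentile) and a summed FPKM of 88.2 in the IgG and 42.9 in the nucleolin library. Pcna was at 16.0 FPKM in the nucleolin library only, Mcm6 and Cdk2 at 31.3 and 20.3 FPKM in the IgG library only, and Aurka at 24.9 and 9.87 FPKM, near the ratio of equal reads. Beside each of these groups, the 4 epithelial markers were in the IgG library only.

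**Figure D3:**
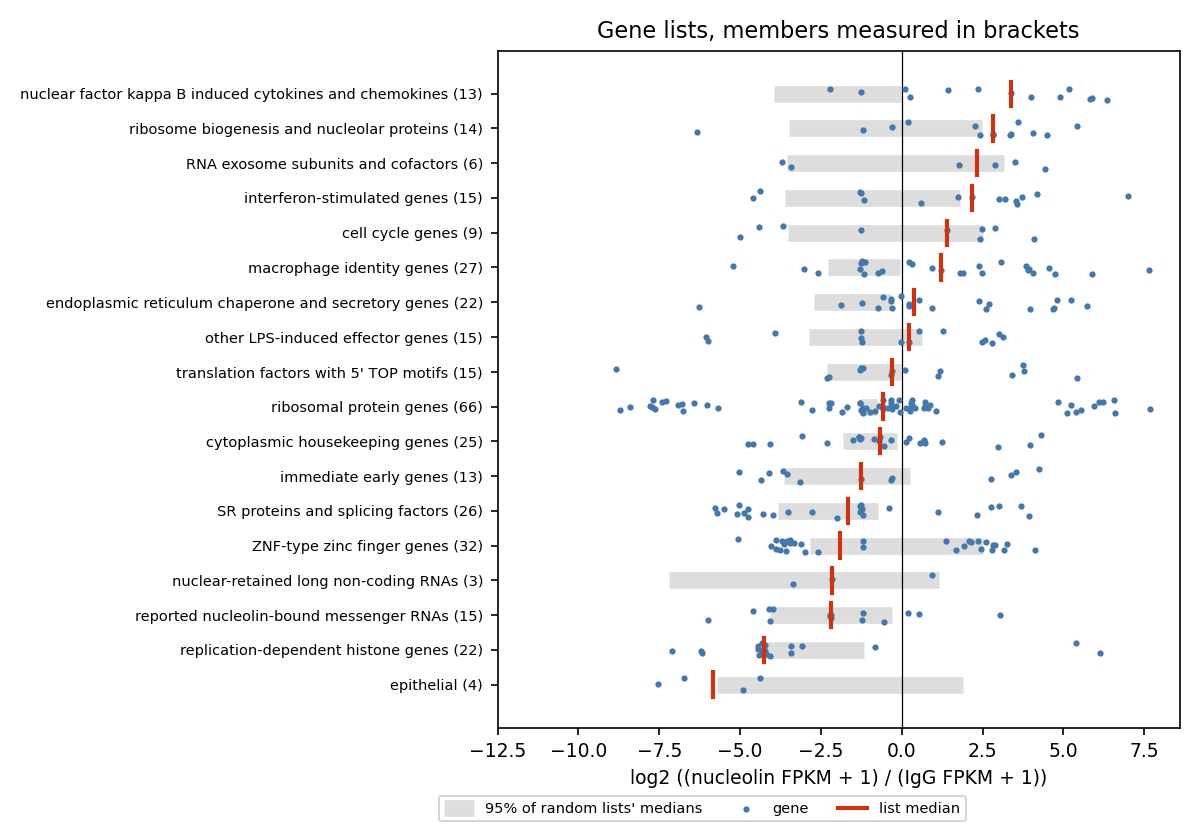
Each row is a gene list fixed beforehand, with the log2 ratio of nucleolin to IgG FPKM (pseudocount 1) on the horizontal axis; blue points are genes, red bars list medians and grey bars the central 95% of the medians of 10000 matched random lists. The medians range from -5.82 (epithelial markers) to 3.38 (cytokines and chemokines).

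The genes measured in both libraries gave the comparisons that did not rest on an absent value; those named here were chosen after their values were seen. The largest ratios toward the nucleolin library were those of P4hb (protein disulfide isomerase, 5.52 times, 18.1 against 99.8 FPKM), Ccl9 (5.31 times, 30.1 against 159.8 FPKM) and Srgn (serglycin, 5.28 times, 57.4 against 303 FPKM). Spp1 (osteopontin, 139 against 512 FPKM), Cd74 (the class II invariant chain, 34.8 against 123 FPKM) and Ccl4 (185 against 501 FPKM) were 3.69, 3.53 and 2.71 times higher. The IgG values of P4hb, Ccl9 and Cd74 lie within the range of the low genes at 1 read in that library (2.70 to 56.6 FPKM). The upper end of that range is set by the limit of 60 FPKM. Genes at the ratio of equal reads reached 178 FPKM. The IgG value of Srgn lies just above the range and may also rest on few reads, so the folds of these genes are uncertain. Toward the IgG library, among the 22 genes above the highest level of equal reads in both libraries, Rps21 (896 against 103 FPKM), Eif1 (838 against 168 FPKM) and Rnh1 (641 against 174 FPKM) were 8.68, 4.98 and 3.69 times higher. Actb (451 against 308 FPKM), Eef1a1 (453 against 486 FPKM) and Cd14 (319 against 207 FPKM) were less than 2-fold apart as deposited. With 1 read set equal between the libraries (a factor of 2.54), the direction of Actb and Cd14 turns. The folds of Eif1 and Rnh1 then fall below 2-fold, and that of Rps21 shrinks. Among the 243 low genes with a matched read pair, the 95% interval of the FPKM ratio lay below 1 for 1 gene, Klf4 (59.5 against 5.84 FPKM, upper bound 0.994), and with 1 read set equal the bound was 2.53. A pair of at most 8 reads can give no interval above 1 as deposited, and none off 1 with 1 read set equal, so these intervals do not show whether the low genes differed.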

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

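The tests in this part were all chosen after the values were seen. Among the 56 rows without a gene symbol, which no comparison used, 2 were at 1 FPKM or more in the nucleolin library and higher there than in the IgG control. A copy of Ubb-ps, a ubiquitin pseudogene, on chromosome 14 was at 266 FPKM in the nucleolin and 42.2 FPKM in the IgG library, and one of Gm5643 on chromosome 15 at 21.8 and 0.00280 FPKM. A row of Eno1b on chromosome 18 went the other way, at 0 FPKM in the nucleolin and 27.1 FPKM in the IgG library.

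The first pattern is the set of gastric secretory genes in the IgG library, although the labels name only a macrophage line. Of 26 gastric gland genes 17 were at 0.1 FPKM or more in the IgG library and 0 in the nucleolin library, and 11 lay above the highest value of any gene at the ratio of equal reads, which argues against single stray reads. Gastric gland, keratinising squamous and smooth muscle genes, which a mouse stomach with its forestomach and muscle wall expresses, were listed for 55.3% of the 47 members whose values had not been seen when the lists were written, against 4.35% of 69 such members of lists for intestine (0 of 12), liver, lung, brain, muscle, testis and kidney, all but the intestinal list written later (7.69% with the pancreatic acinar list); this is consistent with stomach RNA or reads in the IgG library. Pancreas is argued against, because the other acinar enzymes (4 of 22 listed) together came to 1.93% of the level of Clps plus Pla2g1b. Macrophage genes were present too (15 of 35, Cd14 at 319 FPKM). They cannot settle whether the IgG library was stomach alone, since a tissue can hold macrophages of its own. Whether tissue RNA, another library's reads or a mixed sample brought the stomach transcripts stays open, and no biological explanation was tested.

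The second pattern is the large number of 2-fold differences. Of the 2-fold genes 88.0% were at or near 0 in the other library, which restates the pattern: the sampling of few reads and genes absent from 1 library would both give it. If few reads drawn from one shared composition were the whole cause, the shallower IgG library was predicted to list fewer genes. Instead, 280 more genes were found only in the IgG library (1471) than only in the nucleolin library (1191, counting SD of the difference 51.6). Without the 10 highest genes of each library, however, summed FPKM was 2.66 times higher in the IgG library. This is near the 2.54-fold worth of 1 read. Under one shared composition, transcript lengths are the same in both libraries, so read numbers of the other genes would be similar. Without that assumption the read numbers are not known, because the transcript lengths are missing. Under one composition, fewer IgG genes were therefore not to be expected. Similar read numbers would give a difference near 0, so the surplus still argues against one composition as the whole cause. In a simulation, 1 shared composition was sampled at both total depths, with 1 read given the same worth for every gene. On average 1068 genes were 2-fold higher and 633 lower, beside the 1206 and 1812 counted. The draws gave the IgG library fewer reads throughout. They listed on average 1172 genes there and 1913 in the nucleolin library, against 2009 and 1729 in the data. The simulated numbers of listed genes thus differed from the data, so these counts do not show how many differences sampling gives here. Genes of the stomach lists described above (41 of 63 at 0.1 FPKM or more in the IgG library, 1 in the nucleolin library) add to the IgG surplus. A lower number of distinct molecules in the nucleolin library and true differences in bound RNA stay open.

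The third pattern is the positive median of the macrophage and cytokine lists. Their 40 measured members had a median log2 ratio of 1.84, with 19 at or near 0 in the IgG library and 1 in the nucleolin library. Their summed FPKM, which absent values do not bias, had a log2 ratio of 0.45 (95% interval over members -0.08 to 1.14). The interval covers the spread between members, not the sampling of reads. On the deposited scale it includes 0, while equal reads would give -1.35 there. A test against 0 therefore cannot tell members simply not drawn in the IgG library from a difference. Relative to all genes but the 10 highest of each library, the members stood 1.86 higher (1.33 to 2.55), but the lists were chosen for their positive medians, so this value restates the pattern and leaves dilution of macrophage RNA by stomach RNA in the IgG library open. Recovery of these transcripts by the nucleolin antibody would give the same value and stays open too, as untested.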

How the results depend on the processing

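With 1 library per group, no library could be left out, and no paired analysis was possible because each group has 1 library without a replicate number. The counts of 1206 higher and 1812 lower genes stayed within 1.5 times under most settings, and moved as follows. A minimum of 10 FPKM gave 448 higher and 1439 lower genes. At 1 read in each, genes had a median of 17.2 FPKM in the IgG but 6.76 FPKM in the nucleolin library. This floor therefore favours the IgG library, in the lists as well. With genes measured in both libraries only, 20 and 342 remained. Above the highest level of equal reads in at least 1 library 27 and 61 remained. Both settings were chosen after seeing the data, and fewer genes enter these counts by construction. The 4-fold threshold gave 1070 and 1536, and a pseudocount of 5 gave 833 and 1605. Of the 2-fold genes 40.0% were higher as deposited and 34.2% with a pseudocount of 5. Lower genes stayed the majority throughout: the share was 46.4% after centring on the median of all genes (a shift of -1.27), 45.4% with upper quartile scaling, 46.9% without the 10 highest genes and 46.3% with 1 read set equal, against 23.7% at a minimum of 10 FPKM, 5.52% over genes in both and 30.7% above the level of equal reads. After centring, the sign turned for the immediate early genes (0.0109), Aurka (0.0134), Nolc1 (0.0770), Zfp384 (0.0580) and Zfp91Cntf (0.0653). Without the 10 highest genes it turned for the immediate early genes (0.0741), Aurka (0.0727), Cxcl10 (0.0980), Nolc1 (0.0570), Zfp384 (0.0605) and Zfp91Cntf (0.0586), and with 1 read set equal for the immediate early genes (0.0107), Aurka (0.00943) and Cxcl10 (0.0336). These 5 genes were at or near the ratio of equal reads, which such scalings move to about 0. All these turned values lie near 0 and mark no difference, not a reversed direction. Over members measured in both, medians turned for the nucleolar proteins (-0.31), interferon-stimulated genes (-1.21), macrophage identity genes (-0.94), cell cycle genes (-1.25), other LPS-induced genes (-0.02) and endoplasmic reticulum genes (-0.31). All genes in both had a median of -1.19, so a negative sign there does not by itself mark a reversed direction. Only the interferon-stimulated and cell cycle medians lay below that value. The cell cycle median also turned at a minimum of 10 FPKM (-3.67) and as summed FPKM (-1.04), and the median of the other LPS-induced genes as well (-1.26 and -0.56). The ribosomal protein, 5' TOP and housekeeping medians turned positive under all 4 other scalings, with more genes higher than lower in each list, as did Ier3 (-0.30 to 0.96 after centring and 1.02 with 1 read set equal), Ptbp1 (-0.38 to 0.89 in both) and Rn45s (-0.05 to 1.22 after centring). After centring, 9 of the other LPS-induced genes were higher and 3 lower (6 and 6 as deposited), of the endoplasmic reticulum genes 14 and 1 (9 and 3), of the macrophage identity genes 17 and 3 (14 and 8) and of the splicing factor genes 6 and 12 (6 and 19). Without the 10 highest genes, the next 10 held 10.6% of the IgG and 8.84% of the nucleolin library, and ribosomal protein genes 11.9% and 18.2% in place of 4.89% and 1.52%. Without matching on level, 9 of 17 list percentiles moved by 10 points or more: histone (0.24), 5' TOP (77.7), reported target (41.0), exosome (90.6), other LPS-induced (80.5), immediate early (52.8), zinc finger (41.7), endoplasmic reticulum (85.4) and cell cycle genes (80.1). Those of ribosomal protein (90.2), macrophage identity (91.3) and interferon-stimulated genes (92.9) came down by less. Over all settings the values of named genes differed from the reported one by under 1.5 times in 451 cases, moved further in 365 and turned in 11, and list medians in 78, 108 and 9, where turned counts only reported log2 values of at least 1 in size. The turned cases of named genes are the values near 0 given above. The cause was not tested. Depth limits every value: genes at 1 read in each library had a median of 17.2 FPKM in the IgG library. They reached 56.6 FPKM among the genes examined, which were kept below 60 FPKM there.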

Other observations

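Beyond the fixed lists, the IgG library carried a coherent set of squamous epithelial and smooth muscle transcripts; these lists were written after the values were seen. Of 28 genes of keratinising squamous epithelium 17 were listed in the IgG library and 1 in the nucleolin library, among them Krt10 (201 FPKM), Lor (loricrin, 188 FPKM), Krt1 (169 FPKM), Krtdap (167 FPKM) and Krt13 (152 FPKM). Krt14 is also on the fixed epithelial list. Sfn was the member in both, at 30.0 and 11.9 FPKM. Of 9 smooth muscle genes 7 were listed in the IgG library and 0 in the nucleolin library, with Tagln (214 FPKM) and Myl9 (96.0 FPKM) the highest. Of the gastric gland genes, Psca (776 FPKM), Ghrl (ghrelin, 357 FPKM), Atp4a and Atp4b (subunits of the gastric proton pump, 282 and 225 FPKM) and Gif (gastric intrinsic factor, 191 FPKM) were in the IgG library only. No gene of the intestinal (12), lung (10), testis (8) or kidney (8) list was above 0.1 FPKM in either library, while 3 of 17 liver, 1 of 11 muscle and 0 of 11 brain genes were listed in the IgG library. Of 24 pancreatic acinar genes 6 were listed in the IgG library and 0 in the nucleolin library.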
